A study of Mus musculus with 6 samples.

How the data were processed

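Gene expression was measured by RNA sequencing in natural regulatory T cells (nTregs, the thymus-derived CD4 T cells that carry the transcription factor Foxp3) from the spleens of C57BL/6 mice in which the Foxp3 locus also drives a diphtheria toxin receptor and EGFP. Per the labels' protocols, the cells were activated for 2 days on plate-bound antibody to CD3 with soluble antibody to CD28 and IL-2, then kept for 6 h with DMSO vehicle or 100 nM of an agonist of EP4, a receptor for prostaglandin E2. They were then sorted on GFP, RNA was taken with a column kit for small samples, and libraries were made with a stranded, poly(A)-based Illumina kit. The 6 libraries fall into 2 groups of 3, and the group and replicate number of each came from its title. The labels do not say whether the 3 replicates of a group are separate mice, cultures or aliquots, so the p-values measure the spread between these libraries, which may be technical.

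The authors deposited 1 table of gene abundances per library on the mm10 build. Trim Galore and HISAT2 are named in the submitters' processing notes without versions. The program that made the abundances, the annotation release and the strand setting are not given in the sources used here. Per the file headers, each table gives coverage, FPKM (fragments per kilobase of transcript and per 1000000 fragments) and TPM for each feature, and the values were used as deposited. Each table held the same 47643 reference gene identifiers and 19801 to 20833 further loci assembled from that library's own reads. Of the reference identifiers, 47224 are in GENCODE M21 when the version is ignored, and the 39106 with the same version have the same coordinates there. The deposited TPM column sums to 1000000 over the assembled loci alone and to between 1901346 and 1930242 over the whole column, so it was not used. Fragment counts could not be recovered from the files. The deposited coverage and FPKM stood in a constant ratio within a library for 31.5 to 32.7% of rows, to within 0.1%, and this ratio gives the aligned bases behind each library, between 4.32 and 5.65 gigabases. An interval for counting error would need fragment counts and is not given. The precision stated is the spread between libraries.

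The design written before the data were examined assumed counts and named, for normalized values, the fallback used here. FPKM values were analysed as log2(FPKM + 1) for the 12186 reference genes with an FPKM of at least 1 in 3 or more libraries. Fold changes on this scale understate the change of genes with low FPKM. Differences between agonist and vehicle were tested with limma 3.58.1 (moderated test with an intensity trend and robust variances, statmod 1.5.0) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. "Rose", "fell" and "changed" refer to this threshold. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Of the tested genes, 1496 overlap another expressed reference gene on the same strand, and their FPKM may include its reads. Since the strand setting is unknown, reads of a gene and of a partner on the opposite strand may not have been told apart either. 5 genes were listed at 0 in some library and above 5 FPKM in another.

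The replicate numbers 1 to 3 occur in both groups, and whether they pair the libraries was decided before any fit with the number as a block was examined. Deviations of the libraries from their group means, over the tested genes, correlated at 0.512, 0.404 and 0.321 for the pairs numbered 1, 2 and 3. The 6 pairs with different numbers gave correlations from -0.353 to 0.002. Every same-numbered pair was above the limit of 0.1, so the numbers were taken to pair the libraries. The pairing rests on these correlations, since the labels do not state what the number stands for. Deviations sum to 0 within a group, so the correlations are not independent of each other. A block chosen from them in the same libraries favours smaller p-values in the blocked fit. The fit without the block stayed the main one, as fixed beforehand, and the blocked value is printed where it changes a call or moves a count by more than 1.5 times.

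In that design 26 gene lists were fixed from general knowledge of these cells, including markers of other cell types that the sort could hold. The 23 lists with at least 5 tested members were compared with all other tested genes by camera in limma, a competitive test, with a preset correlation between genes of 0.01. The test was run on log2(FPKM + 1) in place of the planned log2 CPM, and p-values were adjusted over the lists. The correlation was also estimated per list, and fry, a rotation test of whether the genes of a list move on balance one way, was run too. The genes named in the text follow a rule fixed beforehand. It takes the 12 highest and 12 lowest fold changes among genes that passed, with a mean FPKM of at least 1 and no overlap between the groups, leaving out unnamed gene models, ribosomal protein genes and antigen receptor segments. It adds up to 4 members of each list with the smallest p among those that passed, and 15 genes given in all cases: Foxp3, Ptger2, Ptger4, Il2ra, Ikzf2, Ctla4, Il10, Ccr8, Tnfrsf9, Crem, Nr4a1, Pde4b, Cd4, Cd8a and Ptprc. Members that passed with the block alone are further examples, chosen after their values were seen, as were the immunoglobulin joining segments, the genes given for other cell types and those of the closing section.

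The tests were checked on simulated data for the same comparison, with 12186 genes and 200 changed genes in each of 5 draws. The fit without the block recovered 71.6% of genes changed 2-fold and 17% of those changed 1.5-fold, and 1.1% of its calls were false. The fit with the block recovered 90.4% and 60.2%, and 7% of its calls were false. Each simulated library was given the mean deviation of its replicate number in the real data, and gene variances came from the blocked fit. A gain from the block was thus built in, and these draws do not test whether the numbers pair the libraries. In 20 further draws with independent genes, in which the cell cycle list was raised by 0.3 in log2, camera called it in 20 draws and called 0 of the 440 other list tests. The 20 draws held neither a replicate effect nor correlation between genes. They cannot show how often camera calls lists falsely in the real libraries.

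The alternatives were a pseudocount of 0.1, no filter, a minimum FPKM of 5, median-ratio and upper quartile scaling, removal of mitochondrially encoded and ribosomal protein genes, the replicate block, each library left out in turn, a test against a 1.5-fold change and a threshold of 0.01. Others were added after the data were seen: deposited coverage divided by aligned bases in place of FPKM, quantile normalization, protein-coding genes only, genes without a same-strand overlap only, each pair left out with the block, and combinations with the block. Assembled loci without a reference gene on their strand were joined across libraries by overlap, and the 594 loci with an FPKM of at least 1 in 3 or more libraries were tested with limma on the same scale.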

Results

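The transcriptome of activated splenic nTregs was measured in 3 libraries from vehicle-treated cells and 3 libraries from cells given 100 nM EP4 agonist for 6 h. The title of the series places the comparison in work on prostaglandin E2 signalling through the receptors EP2 and EP4 and the phenotype of regulatory T cells in tumours. The question here is which transcripts of nTregs differ after EP4 stimulation outside the animal. The vehicle libraries rest on 4.95, 5.65 and 4.49 gigabases of aligned sequence for replicates 1, 2 and 3, and the agonist libraries on 4.98, 4.32 and 4.86 gigabases. Between 11947 and 12259 reference genes had an FPKM of at least 1 in each library. Mitochondrially encoded genes held 4.51 to 6.80% of the summed FPKM of reference genes. Rows named for ribosomal RNA held 0.975 to 1.96% in 5 libraries and 3.15% in agonist replicate 2.

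After 6 h of EP4 agonist, transcripts of the receptors 4-1BB and PD-1 and of single enzymes such as Dgat1 and Got1 were higher in nTregs. Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, rose from 146 ± 58.1 to 468 ± 25.7 FPKM (mean ± SD, n = 3 per group). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 16.3 ± 3.65 to 53.1 ± 4.97 FPKM. Igfbp4, encoding a binding protein for insulin-like growth factors, fell from 21.7 ± 4.26 to 8.50 ± 0.499 FPKM. Foxp3 itself stood at 132 ± 22.0 FPKM with vehicle and 135 ± 16.6 FPKM with the agonist and did not pass the test (limma, adjusted p = 0.938). Of the 12186 genes tested, 42 rose and 6 fell, and each of the 48 had agonist values that lay outside the range of its vehicle values. Such separation was found for 19.4% of tested genes, where chance gives 10% if the 6 libraries are exchangeable, a share that takes no account of the pairing by replicate number. With the replicate number as a block, limma called 1279 genes, 498 higher and 781 lower, and these included the 48. With quantile normalization as well, 519 were higher and 478 lower.

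The fold change was greatest for Ramp3 (ENSMUSG00000041046.7, chromosome 11, 6658521 to 6677475, mm10), which encodes a receptor activity-modifying protein that partners G protein-coupled receptors. It rose from 0.503 ± 0.568 to 11.3 ± 3.20 FPKM, a log2 fold change of 3.06 with a standard error of 0.30 (limma, adjusted p = 0.0165). With a pseudocount of 0.1 its log2 fold change was 4.68 and its adjusted p was 0.0512, in a range of 0.00457 to 0.128 over all alternatives. Dgat1 (ENSMUSG00000022555.11, chromosome 15, 76502015 to 76511951), an enzyme of the last step of triglyceride synthesis, rose from 18.4 ± 1.18 to 75.4 ± 26.6 FPKM, with a log2 fold change of 1.91 and adjusted p = 0.0329. Fosl2 (ENSMUSG00000029135.10, chromosome 5, 32135801 to 32157842), an AP-1 transcription factor, rose from 4.94 ± 1.94 to 20.8 ± 4.01 FPKM, a log2 fold change of 1.91 (adjusted p = 0.0267). The log2 fold change was 1.74 for Tnfrsf9 (ENSMUSG00000028965.13, chromosome 4, 150914562 to 150946102; adjusted p = 0.0409) and 1.66 for Pdcd1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553; adjusted p = 0.0154). Fasl, the death ligand of Fas, rose from 1.43 ± 0.433 to 6.43 ± 1.21 FPKM. Gnal, a G protein alpha subunit that stimulates adenylyl cyclase, rose from 2.72 ± 1.16 to 10.2 ± 1.14 FPKM. Pja1, a ubiquitin ligase, rose from 28.5 ± 6.82 to 73.4 ± 4.93 FPKM, and Got1, the cytosolic aspartate aminotransferase, from 23.6 ± 2.58 to 61.1 ± 7.10 FPKM. Trf, which encodes transferrin, rose from 3.02 ± 0.544 to 9.26 ± 0.570 FPKM, and the splicing factor gene Isy1 from 21.2 ± 2.34 to 54.4 ± 8.21 FPKM. Trf and Isy1 each overlap another gene model on their strand, so part of their signal may belong to that model.

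**Figure D1:**
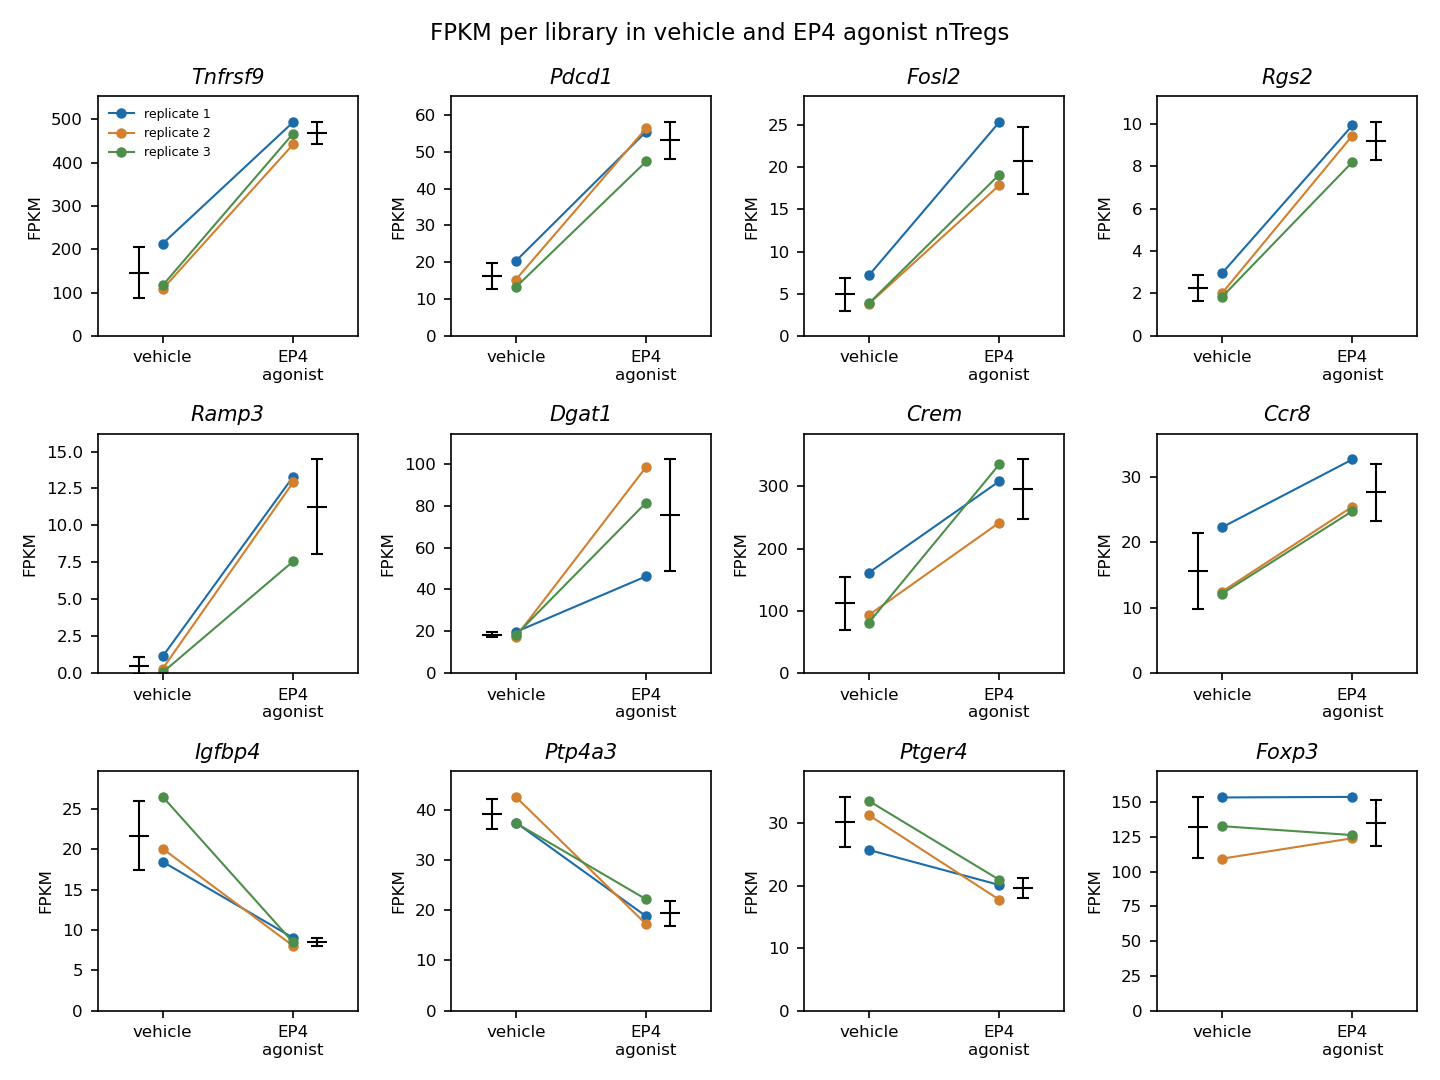
FPKM (vertical axes, linear from 0) of 12 genes in each of the 6 libraries, with lines joining libraries of the same replicate number and black bars giving mean ± SD of each group (n = 3). Tnfrsf9 goes from 146 ± 58.1 to 468 ± 25.7 FPKM and Igfbp4 from 21.7 ± 4.26 to 8.50 ± 0.499 FPKM, and for Tnfrsf9, Fosl2, Crem and Ccr8 the vehicle library numbered 1 is the highest of the vehicle libraries.

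The genes that fell were few in this test. Igfbp4 (ENSMUSG00000017493.12, chromosome 11, 99041244 to 99054392) had a log2 fold change of -1.24 with a standard error of 0.13 (limma, adjusted p = 0.0200). Ptp4a3, a tyrosine phosphatase, fell from 39.2 ± 2.98 to 19.4 ± 2.54 FPKM, a log2 fold change of -0.98 (adjusted p = 0.0205). Serpina3g, a serine protease inhibitor, fell from 21.2 ± 1.83 FPKM to 11.2, 13.7 and 11.1 FPKM in the agonist libraries, a log2 fold change of -0.77 (adjusted p = 0.0401). With upper quartile scaling its adjusted p was 0.0505, in a range of 0.00641 to 0.196 over all alternatives. The other 3 were segments of the immunoglobulin heavy chain locus on chromosome 12. The constant region gene Ighm (113418558 to 113422730) fell from 320 ± 7.76 to 221 ± 4.59 FPKM, with adjusted p = 0.0424. The joining segment Ighj1 fell from 50.4 ± 6.02 to 26.7 ± 1.82 FPKM and Ighj2 from 9.55 ± 1.02 to 4.63 ± 0.493 FPKM.

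The number of genes passing limma's test depended on the libraries kept. It was 133 without vehicle replicate 1, 4 without agonist replicate 1, 5 without agonist replicate 3, and 0 without vehicle replicate 2, vehicle replicate 3 or agonist replicate 2, where 1033, 1115 and 1606 genes had an unadjusted p under 0.05, and with the block it was 241 without pair 1, 0 without pair 2 (2557 unadjusted) and 1 without pair 3. Without a filter on low FPKM, limma called 2 genes of 26424, and against a 1.5-fold change it called 0 (66 unadjusted).

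Genes of the cyclic AMP and CREB response, the pathway downstream of the stimulatory G protein to which EP4 couples, were higher as a group. Of 45 tested members, 4 rose and 0 fell, and adjusted over the list alone 12 rose and 1 fell. With the block 17 rose and 1 fell. The mean log2 fold change was 0.36, and camera gave an adjusted p of 2.77e-09. With an estimated correlation the adjusted p was 0.412, and 0.185 with the block as well. The 4 were Fosl2, Rgs2, Dusp4 and Sik1. Rgs2, a brake on G protein signalling, rose from 2.26 ± 0.601 to 9.20 ± 0.894 FPKM (adjusted p = 0.0154). Dusp4, a MAP kinase phosphatase, rose from 65.7 ± 9.09 to 141 ± 6.26 FPKM, and Sik1, a kinase induced by CREB, from 3.74 ± 0.696 to 8.96 ± 1.19 FPKM. Crem, a cyclic AMP-responsive transcription factor, had 112 ± 43.2 FPKM with vehicle and 295 ± 48.2 FPKM with the agonist. Its adjusted p was 0.0858 without the block and 0.0300 with it. The phosphodiesterase gene Pde4b had 7.44 ± 1.63 and 10.9 ± 1.23 FPKM (adjusted p = 0.238, and 0.0255 with the block), and Pde4d had 13.98 ± 4.78 and 28.1 ± 3.12 FPKM (0.131, and 0.0210 with the block). Nr4a1, an early response gene, had 9.49 ± 6.43 and 12.5 ± 6.46 FPKM and did not pass (adjusted p = 0.723, and 0.0897 with the block).

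Among 10 tested genes of prostaglandin receptors and metabolism, 0 rose and 0 fell, and 1 fell when adjusted over the list alone. With the block 2 fell, Ptger4 and the transporter gene Abcc4. Ptger4, which encodes EP4 itself (chromosome 15, 5206661 to 5244187), had 30.2 ± 4.04 FPKM with vehicle and 19.6 ± 1.66 FPKM with the agonist, a log2 fold change of -0.59 (limma, adjusted p = 0.109, and 0.0310 with the block). Ptger2, which encodes EP2, had 4.05 ± 1.09 and 4.83 ± 1.13 FPKM (adjusted p = 0.675). The list as a whole was not shifted (camera, adjusted p = 0.380).

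Genes of Treg identity and suppression were higher as a group, while Foxp3 and Il2ra differed by less than the spread between replicates. Of 33 tested members, 0 passed over all genes, and 11 rose and 2 fell when adjusted over the list alone. With the block 14 rose and 2 fell. The mean log2 fold change was 0.27 (camera, adjusted p = 1.27e-05), and the adjusted p was 0.347 with an estimated correlation and 0.185 with the block as well. Il2ra, the high-affinity IL-2 receptor chain, had 848 ± 69.2 FPKM with vehicle and 850 ± 78.1 FPKM with the agonist (adjusted p = 0.995). Ctla4, an inhibitory receptor central to suppression by Tregs, had 242 ± 35.5 and 380 ± 56.7 FPKM (adjusted p = 0.156, and 0.0711 with the block). With the block Ctla4 passed limma's test on coverage in place of FPKM (adjusted p = 0.0207) and when pair 1 was left out (adjusted p = 0.0422). With the block the co-inhibitory receptor gene Tigit rose from 64.1 ± 10.4 to 90.7 ± 14.7 FPKM and Gpr83 from 68.0 ± 10.6 to 110 ± 8.52 FPKM (adjusted p = 0.0166 and 0.0180). Ikzf2, which encodes the transcription factor Helios, had 29.7 ± 4.29 and 36.8 ± 5.21 FPKM (0.410, and 0.0268 with the block). Il10 had 5.90 ± 3.38 and 8.43 ± 3.27 FPKM (0.574, and 0.0465 with the block). Socs2 and Itgae were the 2 members that fell with the block. Foxp3, Il2ra and Ctla4 each overlap another gene model on their strand.

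The list of effector and tumour-infiltrating Treg genes, compiled from general knowledge and not from these libraries, was also higher. Of its 40 tested members, 4 rose and 0 fell, and adjusted over the list alone 10 rose and 3 fell. With the block 19 rose and 3 fell. The mean log2 fold change was 0.29 (camera, adjusted p = 3.87e-07). The adjusted p was 0.0693 with an estimated correlation and 0.185 with the block as well. Without the block fry gave 0.00169 for this list and for no other list a value under the threshold. Its adjusted p was 0.214 for the cyclic AMP list, 0.235 for Treg identity, 0.107 for the co-stimulatory and co-inhibitory receptors, 0.0775 for IL-2 targets, 0.442 for the cell cycle, 0.214 for glycolysis and 0.458 for both mitochondrial lists. With the block fry gave 0.00789 for effector Treg, cyclic AMP, IL-2, cell cycle and TGF-beta genes (TGF-beta 0.645 without it). It gave 0.00833 for Treg identity and glycolysis, and 0.0118 for the co-stimulatory and co-inhibitory receptors. No other list passed fry with the block, and the nuclear and mitochondrially encoded lists had 0.265 and 0.431. Besides Tnfrsf9 and Pdcd1, the adaptor gene Samsn1 rose from 52.5 ± 2.18 to 80.7 ± 5.14 FPKM (adjusted p = 0.0329). Hif1a, the oxygen-regulated transcription factor, rose from 73.6 ± 3.07 to 110 ± 7.38 FPKM (adjusted p = 0.0498). Ccr8, a chemokine receptor found on Tregs in tumours, had 15.6 ± 5.77 FPKM with vehicle and 27.6 ± 4.38 FPKM with the agonist (adjusted p = 0.195, and 0.0218 with the block). The 3 members that fell with the block were Batf, Irf4 and Itgae. Batf and Irf4 are transcription factors of effector Treg differentiation. Batf had 65.7 ± 9.50 and 48.0 ± 5.87 FPKM and Irf4 33.3 ± 5.80 and 22.1 ± 1.31 FPKM (adjusted p with the block 0.0179 and 0.0253).

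Co-stimulatory and co-inhibitory receptors were shifted upward (37 tested members, mean log2 fold change 0.32, camera adjusted p = 3.73e-07; adjusted p = 0.320 with an estimated correlation and 0.185 with the block as well). Pdcd1, Fasl and Tnfrsf9 rose and 0 members fell. Adjusted over the list alone 6 rose and 1 fell, and with the block 12 rose and 2 fell. With the block Tnfrsf4, which encodes OX40, rose from 354 ± 54.6 to 527 ± 45.0 FPKM and Icos from 121 ± 14.8 to 163 ± 26.9 FPKM, whereas Btla fell from 8.35 ± 0.608 to 6.02 ± 0.768 FPKM. Targets of IL-2 and STAT5 had a mean log2 fold change of 0.11 over 26 tested members (camera, adjusted p = 0.00901; adjusted p = 0.320 with an estimated correlation, and 0.0113 with the block). With the block and an estimated correlation camera's adjusted p was 0.253. With coverage in place of FPKM the adjusted p was 0.0585, and 0.0816 with the block. None of them passed singly, adjusted over the list alone 6 rose and 2 fell, and with the block 7 rose and 5 fell. The risers included Nfil3, from 23.2 ± 2.12 to 35.8 ± 1.78 FPKM, and Il7r, from 9.56 ± 0.723 to 14.3 ± 0.770 FPKM. Lta, the gene of the cytokine lymphotoxin alpha, fell from 227 ± 19.2 to 153 ± 6.46 FPKM with the block.

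Lists near the threshold without the replicate block met it with the block and, for each, in some alternatives without it. Chemokine receptors and homing genes had an adjusted camera p of 0.0537, and of 0.0223 with the block. Of 27 members 0 passed over all genes, 1 rose when adjusted over the list alone, and 4 rose and 1 fell with the block. T helper cytokines and lineage factors had an adjusted p of 0.05001, and of 0.0120 with the block. Of 13 members 1 rose, 4 rose and 2 fell when adjusted over the list alone, and 6 rose and 1 fell with the block. The riser was Il12rb2, a chain of the IL-12 receptor, from 4.22 ± 0.850 to 11.5 ± 1.11 FPKM (limma, adjusted p = 0.0205). Genes of the TGF-beta response had an adjusted p of 0.05001, and of 0.00751 with the block. Of 16 members 0 passed over all genes or over the list alone, and 6 rose and 1 fell with the block. Heat shock genes had an adjusted p of 0.05001, and of 0.00921 with the block. Of 16 members 0 passed over all genes or over the list alone, and 6 fell with the block, among them Hspd1, from 107 ± 30.6 to 74.1 ± 14.7 FPKM. With the block and an estimated correlation, the adjusted p of these lists was 0.274, 0.337, 0.253 and 0.580 in the order given. Without the block, T helper, TGF-beta and heat shock genes passed with no filter (adjusted p = 0.0238, 0.0191 and 0.0146) and at an FPKM of at least 5 (adjusted p = 0.0213, 0.0272 and 0.0230). With coverage T helper and heat shock genes passed, both at 0.0230, as did T helper genes without overlapping models (0.0313) and heat shock genes without mitochondrial and ribosomal protein genes in the test (0.0468). Leaving out 1 library also took the lists past the threshold without the block. This was vehicle replicate 3 for chemokine receptors, agonist replicate 1 or 3 for T helper genes, and vehicle replicate 1 or agonist replicate 2 for TGF-beta and heat shock genes.

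Cell cycle genes were lower as a group, by a small amount per gene. The mean log2 fold change over 46 tested members was -0.19 (camera, adjusted p = 6.82e-06), and it was -0.18, -0.19 and -0.21 in the pairs numbered 1, 2 and 3. The adjusted p was 0.632 with an estimated correlation and 0.185 with the block as well. No member passed over all genes or over the list alone without the block, and with the block 21 fell and 0 rose. With the block Uhrf1, needed for maintenance of DNA methylation at replication, fell from 150 ± 22.0 to 111 ± 13.9 FPKM, Mcm2, a subunit of the replicative helicase, from 98.3 ± 13.5 to 80.1 ± 9.47 FPKM, and Cdc20, an activator of the anaphase-promoting complex, from 74.5 ± 4.14 to 58.3 ± 3.43 FPKM. Their adjusted p with the block was 0.0180, 0.0301 and 0.0208.

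Glycolysis and hypoxia genes were shifted upward (36 tested members, mean log2 fold change 0.15, camera adjusted p = 5.82e-05; adjusted p = 0.347 with an estimated correlation and 0.185 with the block as well). Hif1a rose, 3 members rose when adjusted over the list alone, and with the block 6 rose and 1 fell. Of the monocarboxylate transporters, with the block Slc16a3 rose from 17.0 ± 0.977 to 30.3 ± 6.77 FPKM and Slc16a1 fell from 11.4 ± 3.01 to 7.58 ± 1.88 FPKM. Nuclear genes of oxidative phosphorylation had a mean log2 fold change of -0.08 over 37 members (camera, adjusted p = 0.0433; adjusted p = 0.785 with an estimated correlation, and 0.0130 with the block), and 0 members passed in either fit. Camera's adjusted p was 0.580 with the block and an estimated correlation. The mean was -0.19 in pair 1 and -0.02 and -0.04 in pairs 2 and 3. The call passed in 9 of 27 alternatives. It was lost with the block when pair 1 was left out (adjusted p = 0.505), and without the block when agonist replicate 1 was left out (adjusted p = 0.865). Quantile normalization lost it in both fits, at an adjusted p of 0.378 and of 0.273 with the block. Without the block it was also lost under median-ratio and upper quartile scaling (adjusted p = 0.0693 and 0.0758), at an FPKM of at least 5 (0.0910), without mitochondrial and ribosomal protein genes (0.0622) and with coverage (0.0585). It was lost too with protein-coding genes alone (0.0535), without overlapping models (0.0511), and without vehicle replicate 1, vehicle replicate 2 or agonist replicate 3 (adjusted p = 0.0952, 0.212 and 0.107). The 13 mitochondrially encoded genes had a mean of 0.19 (camera, adjusted p = 0.00157; adjusted p = 0.632 with an estimated correlation, and 0.00669 with the block). That mean was 0.38 and 0.29 in pairs 1 and 2 and -0.11 in pair 3, and 0 members passed in either fit. Camera's adjusted p was 0.580 with the block and an estimated correlation. The call was lost without vehicle replicate 1 (adjusted p = 0.187) and without agonist replicate 2 (adjusted p = 0.0965). With the block it was lost when pair 1 or pair 2 was left out (adjusted p = 0.118 and 0.0688) and under quantile normalization (adjusted p = 0.0511).

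The other lists did not pass camera in either fit. Adjusted p was 0.773 for NF-kB targets and components, 0.372 for the early response to the T cell receptor, 0.294 for naive and memory T cell genes, 0.806 for cholesterol and lipid synthesis and 0.372 for the type I interferon response. It was 0.380 for adhesion, cytoskeleton and migration, 0.491 for the integrated stress and amino acid response and 0.380 for apoptosis and p53 targets. Over all genes, the members of these lists that passed were Tnfrsf9 in the early response list, Igfbp4 in the naive and memory list and Aldh18a1, an enzyme of proline synthesis, which overlaps another gene model and rose from 43.6 ± 0.679 to 66.5 ± 3.43 FPKM (limma, adjusted p = 0.0267). Adjusted over the list alone, the numbers that rose and fell were 0 and 1 for NF-kB, 2 and 1 for the early response, 1 and 1 for naive and memory genes, 0 and 0 for cholesterol and lipid synthesis and 1 and 2 for interferon. They were 1 and 0 for adhesion, 1 and 0 for the stress response and 0 and 1 for apoptosis and p53. With the block 5 rose and 3 fell in the NF-kB list, 7 rose and 3 fell in the early response list, 3 rose and 2 fell in the naive and memory list and 2 rose and 3 fell in the interferon list. The stress list had 2 risers and 7 that fell with the block, and the apoptosis and p53 list 3 and 7. The adhesion list had 1 and 2, and the cholesterol list 0 and 1. For NF-kB, early response and cholesterol genes, the mean, median and direction of the test did not share a sign. Without agonist replicate 1 the cholesterol list passed as higher (adjusted p = 0.00291), with a mean log2 fold change of 0.06 in place of -0.04, and the apoptosis and p53 list passed as lower (adjusted p = 0.0211). With the block the adhesion list passed when pair 2 was left out (adjusted p = 0.0386) and the naive and memory list with coverage (adjusted p = 0.0389).

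Some markers of other cells were present in the sorted libraries. Cd74, the class II invariant chain, had 17.5 ± 7.34 FPKM with vehicle and 20.4 ± 8.47 FPKM with the agonist, and Nkg7, a gene of cytotoxic cells, 12.2 ± 4.57 and 10.6 ± 3.43 FPKM. Cd8a stood at 0.222 ± 0.188 FPKM with vehicle and 0.288 ± 0.190 FPKM with the agonist, under the limit for testing. Cd8b1, of the same list, was higher than Cd8a, with 4.53 ± 0.975 and 5.02 ± 1.10 FPKM. Cd4 had 114 ± 13.5 and 129 ± 17.0 FPKM and the leukocyte marker gene Ptprc 221 ± 36.0 and 261 ± 37.5 FPKM, and neither passed (limma, adjusted p = 0.567 and 0.535). With the block and coverage in place of FPKM both passed as higher (limma, adjusted p = 0.0410 and 0.0326). Cd4 also passed with the block and quantile normalization (adjusted p = 0.0464). Of the myeloid and dendritic cell markers, 7 reached the limit for testing, with 0 passing in either fit and an adjusted camera p of 0.179. That list passed as higher without vehicle replicate 2 (adjusted p = 0.0468) and without agonist replicate 3 (adjusted p = 0.0142), and with the block when pair 2 or pair 3 was left out (adjusted p = 0.0192 and 0.0410). The lists for B cells, for CD8 T and NK cells and for granulocytes, mast cells and erythroid cells had 3, 4 and 3 tested members and were not tested as lists. Of the B cell markers Ighm fell, while Cd79a had 0.754 ± 0.174 and 0.966 ± 0.284 FPKM and Cd79b 4.90 ± 0.271 and 3.73 ± 0.760 FPKM. With the block, Ltf rose from 14.7 ± 3.52 to 23.9 ± 5.52 FPKM and the haemoglobin gene Hba-a1 fell from 3.50 ± 2.11 to 1.78 ± 1.04 FPKM in the granulocyte, mast and erythroid list. S100a8 and S100a9, of that list, were at 0 FPKM in all 6 libraries.

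**Figure D2:**
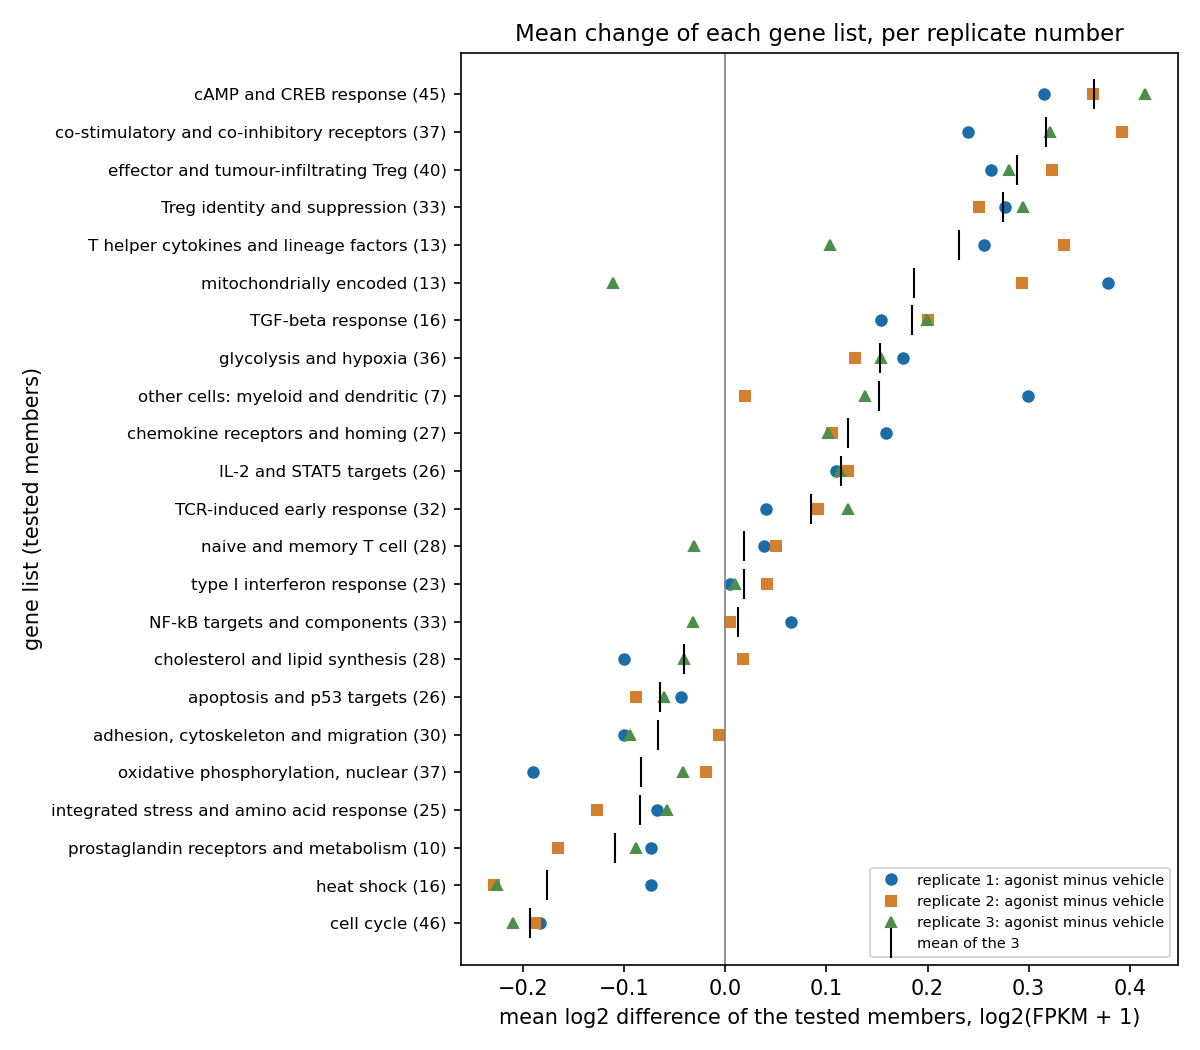
Mean log2 difference between agonist and vehicle, on log2(FPKM + 1), over the tested members of each of 23 gene lists (horizontal axis), with 1 symbol for each replicate number and a bar at the mean of the 3. The cyclic AMP and CREB list lies at 0.36 and the cell cycle list at -0.19 with the same sign for each number, and the mitochondrially encoded list has a mean of -0.11 for number 3 against 0.38 and 0.29 for numbers 1 and 2.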

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

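Signals outside the annotated genes were looked for among the loci assembled from each library's own reads that have no reference gene on their strand. Of 594 such loci tested with limma, 4 had an adjusted p under the threshold (39 an unadjusted p under 0.05), and 0 passed with the replicate block (38 unadjusted). A locus on chromosome 17 (31643844 to 31644715, mm10, strand not assigned) lies 2367 bases from U2af1. It had 15.5, 28.8 and 18.5 FPKM in agonist replicates 1 to 3, a mean of 20.9. No vehicle library had a locus that was joined to it, and it is listed at 0 there (limma, adjusted p = 0.00210, and 0.0802 with the block). A locus on chromosome 13 (21765635 to 21766246, strand not assigned) lies 2879 bases from the non-coding gene Gm11274. It had 7.79, 8.33 and 8.88 FPKM in the agonist libraries, a mean of 8.33, and is likewise listed at 0 in the vehicle libraries (adjusted p = 0.00206, and 0.0802 with the block). A value of 0 was filled in where a library had no locus free of reference genes at that place with the same strand label. Reads below the limit of assembly, a locus that reached a reference gene or one with another strand label are not excluded. The adjusted p-values of these loci rest on such filled values. In the opposite direction, a locus on chromosome 13 (67890560 to 67893570) had a mean of 3.57 ± 0.680 FPKM in the vehicle libraries and one on chromosome 10 (118238383 to 118238754) a mean of 1.67 ± 0.184 FPKM, and both are listed at 0 with the agonist.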

How the results depend on the processing

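The mean log2 fold change of the cholesterol and lipid synthesis list, -0.04 with all libraries, was 0.06 without agonist replicate 1, where the list passed at an adjusted p of 0.00291. Camera's direction for that list was upward in both. No other result had the opposite sign past the threshold, and where the 48 genes were tested their sign was kept in each alternative, those chosen after seeing the data (coverage, quantile normalization, the biotype and overlap filters, pairs left out and combinations with the block) included. Counts below are of genes changed, higher and lower, against 48, 42 and 6. With the replicate block they were 1279, 498 and 781, so the share of calls that were higher was 38.9% in place of 87.5%. That share was 52.1% with the block and quantile normalization (997, 519 and 478) and 44.0% with the block and median-ratio scaling (1149, 506 and 643). Coverage in place of FPKM gave 86, 77 and 9, and 2155, 793 and 1362 with the block. Without a filter they were 2, 2 and 0 over 26424 genes. At an adjusted p under 0.01 they were 2, 2 and 0, and 0, 0 and 0 with the block, where the smallest adjusted p was 0.0133. Against a 1.5-fold change limma's treat called 0, 0 and 0 in both fits (66 and 115 genes at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 133 genes changed, 0 to 107 higher and 0 to 26 lower: 133 without vehicle replicate 1, 4 and 5 without agonist replicates 1 and 3, and 0 without vehicle replicate 2, vehicle replicate 3 or agonist replicate 2. With the block and pair 1 left out the counts were 241, 151 and 90, with pair 2 left out 0, 0 and 0 and with pair 3 left out 1, 1 and 0. Fewer libraries leave fewer degrees of freedom, and which part of these falls that accounts for was not tested.

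Of the 23 lists, 9 passed camera, 13 with the replicate block (alone, with median-ratio scaling or with coverage), 14 with the block and pair 2 or pair 3 left out, and 8 to 12 in the other alternatives that kept the preset correlation. With an estimated correlation 0 passed, with or without the block, and fry called 1 list, and 8 with the block. Over all alternatives for the named genes, 586 values stayed on their side of the threshold, 175 lost it and 34 gained it. For the lists these numbers were 517, 49 and 53. For limma on the named genes and for camera and fry on the lists, the replicate block alone changed no other call than those given with the results. The cause of the other changes was not tested. A control for gene length and the tests that need counts were not run, since the files give neither, and scaling by library size alone is what FPKM already holds. No scaling moved the median log2 fold change of all genes by more than 0.1. Fragment counts are unknown, so the limit that depth sets could not be computed.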

Other observations

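The lists in this part were written after the table of genes had been seen. Genes of ribosome biogenesis were lower in the agonist libraries as a group. Over 51 tested members of a list of 52, the mean log2 fold change was -0.40, and it was -0.335, -0.434 and -0.423 in pairs 1, 2 and 3. In all 3 pairs 50 members were lower and 1 was higher. With the replicate block limma called 34 lower and 1 higher, and without it 0 lower and 1 higher. Examples with the block were Gnl3, a nucleolar GTPase, from 21.2 ± 5.59 to 11.9 ± 3.39 FPKM, Rrp9, a component of the small nucleolar RNA machinery, from 19.4 ± 3.35 to 11.7 ± 1.70 FPKM, and Nop56 from 101 ± 15.4 to 77.0 ± 10.9 FPKM. The exception was Riok1, a kinase of small-subunit maturation, which rose from 21.02 ± 0.550 to 42.3 ± 1.09 FPKM (limma, adjusted p = 0.00752). Camera gave p = 1.45e-15 with the preset correlation, p = 0.184 with an estimated correlation and p = 0.0728 with the block and an estimated correlation, all unadjusted and on a list that some of its members had prompted. Under the other scalings the mean nearest to 0 was -0.365.

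The Gimap family, GTPases of lymphocyte survival encoded in a cluster on chromosome 6, moved the other way. All 8 tested members were higher in each of the 3 pairs, with a mean log2 fold change of 0.52. Gimap7 rose from 51.1 ± 4.34 to 90.6 ± 4.39 FPKM (limma, adjusted p = 0.0200), and with the block 7 of the 8 rose. Gimap3 had 186 ± 27.7 and 286 ± 30.7 FPKM and Gimap4 332 ± 30.1 and 479 ± 45.6 FPKM. Camera gave p = 2.18e-11, p = 0.00422 with an estimated correlation and p = 0.0641 with the block and an estimated correlation. Under the other scalings the mean nearest to 0 was 0.535. Gimap7 overlaps another gene model on its strand, and Gnl3 and Nop56 hold small nucleolar RNA genes.

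Of the tests in the next paragraphs, those of scaling, of the correlation of the libraries numbered 1, of the direction of genes within pair 1, of the scores with pair 2 or pair 3 held out and of the block's list count were chosen after the result had been seen. Exposure and mislabelling of vehicle replicate 1 were first 1 explanation with 1 limit on the score, and were parted after the score had been seen.

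Transcripts of the immunoglobulin heavy chain locus were lower with the agonist in cells sorted on Foxp3-driven GFP, a gate that B cells should not pass. Ighm fell from 320 ± 7.76 to 221 ± 4.59 FPKM, and with the block 5 segments of the locus passed, all lower. Loss of contaminating B cells is argued against, because the median vehicle FPKM of Cd79a, Cd79b, Igkc, Cd74 and Ms4a1 was 1.10% of that of Ighm, and of these 5 only Cd79b had a lower mean with the agonist, 3.73 ± 0.760 against 4.90 ± 0.271 FPKM (limma, adjusted p = 0.336). Scaling is argued against too, since the Ighm log2 fold change nearest to 0 over 3 other scalings was -0.495. A hypothesis that stays open is that the locus is transcribed without rearrangement in the T cells themselves and less so after EP4 stimulation, which these files may not be able to test.

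Cell cycle genes were lower with the agonist as a group, by a small amount in each pair (camera, adjusted p = 6.82e-06; adjusted p = 0.632 with an estimated correlation and 0.185 with the block as well). Without the block 0 of 46 members passed. Scaling of the libraries is argued against for the list and for its 22 genes of S phase, whose means nearest to 0 over 3 other scalings were -0.139 and -0.185, but it stays open for the 24 genes of G2 and mitosis, where that mean was -0.098 against a limit of -0.1 and pair means of -0.156, -0.142 and -0.165. A single deciding pair is argued against by the highest pair mean of the list, -0.18. An effect of the EP4 agonist stays open, as untested apart from the grouping itself.

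On 241 genes called from pairs 2 and 3 alone, scored from 0 at their vehicle mean to 1 at their agonist mean, vehicle replicate 1 had a median of 0.549 and agonist replicate 1 of 1.22. That score holds the other vehicle libraries near 0. Pair 2 and pair 3 were therefore held out in the same way, on the 241 genes of lowest p in the 2 other pairs. Vehicle replicates 2 and 3 then had -0.255 and -0.077. For these 2 scores the 0 point is a vehicle mean that includes vehicle replicate 1, so values below 0 are partly built in. Of their 241 genes, 0 passed limma's test with pair 2 held out and 1 with pair 3 held out. The 2 scores are therefore no even comparison for 0.549. Over all tested genes each agonist library correlated most with the vehicle library of its own number. For agonist replicates 2 and 3 the lead over vehicle replicate 1 was narrow, 0.984 against 0.983 and 0.9843 against 0.984. Vehicle replicate 1 correlated more with agonist replicates 1 to 3 (0.9862, 0.983 and 0.984) than with vehicle replicates 2 and 3 (0.981 and 0.9825). Of the 241 genes called from pairs 2 and 3, 97.5% moved in pair 1 as in the other pairs. Their median log2 difference was 0.51 in pair 1 against 0.70. This argues against mislabelled agonist-treated cells with as strong a response as agonist replicate 1. These genes may move together, so a mislabelled library with a weaker response could give such a share too and is not excluded by it. Mice of another sex are argued against, as the means of Xist per number differed by at most 1.17-fold, and the Y-linked genes summed to 0 FPKM in 5 libraries and to 0.000247 FPKM in vehicle replicate 3. Exposure of vehicle replicate 1 to some agonist, and a difference shared by both libraries numbered 1, whose deviations correlated at 0.512, both stay open, and either could raise the spread between vehicle libraries.

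The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 48 genes, as many as 1 of the 10 splits (itself), and the highest other gave 1. Of the 4 splits that part every pair, 1 gave as many genes with the block as the real 1279 and the highest other gave 0, and 1 gave as many lists as the real 13, with 6 as the highest other. Without the block, the other splits that part every pair gave 6, 5 and 6 lists against 9 in the real one. Over all splits, 5 of the 10 gave at least the 9 lists of the real one, and the highest other gave 15. That split set the libraries numbered 1 and agonist replicate 3 against the rest, and had 1915 genes at an unadjusted p under 0.05 against 1701 in the real split. With agonist replicate 2 in place of agonist replicate 3 there were 1446, and with vehicle replicate 2 or 3 there were 532 or 562. These splits mix treatment with replicate number. Their counts do not tell a structure by number from a vehicle replicate 1 that lies near the agonist libraries.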
